A study of Mus musculus with 8 samples.

How the data were processed

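Total RNA from the striatum of 4 R6/2 and 4 wild-type mice was labelled with biotin and hybridised to Affymetrix arrays, 1 array per mouse, per the labels' protocols. The deposited values are log2 expression values per probe set, and the authors processed the arrays with RMA and the affy package, per the submitters' processing notes, which give no versions. RMA subtracts background, normalizes arrays together and summarises the probes of a set; which arrays were normalized together is not given in the sources used here. The values ranged from 2.57 to 14.49, no columns were identical, and no column was left unused. Groups and mouse numbers came from the sample titles, and the groups share no numbers, so no pairing was possible. The design text names 4 R6/2 and 5 wild-type mice, and the fifth wild-type mouse was not analysed here.

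The table held 45101 probe sets, 64 of them controls that were left out of all tests. Gene names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and were not named, and 9160 had no entry and are unnamed here. Symbols were checked against RefSeq genes of GRCm38.p6 by Entrez ID, with 34741 matches; no genome build is named with the values and no coordinates are given. For each of the 18193 genes, the probe set with the highest mean over all arrays was used, and 9010 genes had more than 1 probe set. Other probe sets of a named gene are given where their direction was the opposite, and for some genes where they moved less or more. Among the 3276 other probe sets of called genes, 741 had the opposite sign and 23 were called in the opposite direction.

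Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a constant prior, 1 model with the 8 arrays), and p-values were adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05. Standard errors are the moderated errors of the log2 difference, R6/2 minus wild-type, and a fold is 2 raised to its size. Before the data were examined, 31 gene lists (cell types, pathways and complexes) were fixed and tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives, each adjusted over the 31 lists. Camera compares a list with all other genes; fry asks whether the members of a list move one way on balance. The score of a list on an array is the mean over its members of the value minus the wild-type mean. Direct and indirect lists were compared by the difference of their scores with an exact 2-sided permutation test over 70 arrangements. Where the lower group's mean lay at or below the highest Y-linked value on any array, the fold is given as a minimum, against the mean over that group's arrays of the higher of the gene's value and that same value. Gene list sizes in the text are the members with a named probe set.

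The genes named in the text were chosen by a rule set beforehand: the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 called members with the smallest adjusted p of each list (or, where none was called, the 2 with the highest mean), and 13 fixed genes of the striatum and of Huntington's disease, 12 of which had a named probe set. Other genes are said to be named after their values were seen.

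The alternatives tried were quantile normalization over the 8 arrays, centring of each array on its median, leaving out the dimmest 40% of genes or probe sets, the mean of all probe sets of a gene, leaving out probe sets whose IDs end in _s_at or _x_at, an intensity trend with robust moderation, array weights, no moderation, the 2 other list tests, and leaving out each array. A fit with the per-array mean of the cortical projection neuron list as a covariate was added after the data had been seen. Arrays were checked by their 3' minus 5' control signals, their correlations, sex-linked genes and a principal component analysis. On simulated data with the means and spreads of the real genes (5 simulations of 18193 genes with 200 changed genes each, wild-type against R6/2), 58.5% of the genes with a log2 change of 0.5, 96.4% of those with 1 and 100% of those with 2 were called in the right direction, and 5.46% of all calls were unchanged genes. The simulated noise was independent between genes, and fewer genes changed than the 2781 called in the data. These rates therefore do not cover differences between arrays that many genes share. Dim probe sets lie close to background, where RMA compresses differences. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.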

Results

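Gene expression was measured in the striatum, the forebrain region made up mostly of medium spiny projection neurons, of 4 R6/2 mice and 4 wild-type mice, with 1 array per mouse. R6/2 mice carry a transgene with the start of the human huntingtin gene and an expanded CAG repeat, and are a widely used model of Huntington's disease. All 8 mice were labelled as female animals of 12 weeks (85 days) on a mixed C57Bl/6 and CBA background. The wild-type mice were numbered 42, 48, 54 and 63 and the R6/2 mice 64, 65, 70 and 78. The labels number each mouse separately, so the p-values measure the spread between these animals. The design text names 5 wild-type mice, and the fifth was not analysed here. The comparison asked which striatal transcripts differed between the genotypes at this age.

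Values were log2 intensities on a common scale. Array medians lay between 5.08 and 5.13, correlations between arrays ranged from 0.983 to 0.994, and the number of arrays limits the precision of each value. Xist, which is transcribed from the inactive X chromosome, lay between 10.84 and 11.64 on every array, while 9 probe sets of Y-linked genes lay between 2.77 and 3.67, which matches the sex in the labels. The first principal component, with 44.3% of the variance, placed all 4 R6/2 arrays on one side of all 4 wild-type arrays. The genotype labels could not be checked from the mouse huntingtin gene: Htt differed by -0.043 ± 0.075 (log2, SE, adjusted p = 0.751), and the transgene is of human sequence.

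In the striatum of R6/2 mice, 32 of 39 measured genes shared by medium spiny neurons had lower transcript levels. The largest fall between levels above background was that of Ryr1, the calcium release channel of the endoplasmic reticulum, from 8.34 ± 0.45 in wild-type to 4.70 ± 0.51 in R6/2 striatum (log2, SD, n = 4 each), a 12.4-fold difference. Scn4b, a sodium channel subunit, was 4.69-fold lower, and Penk, the precursor of enkephalin, was 2.45-fold lower, going from 12.51 ± 0.16 to 11.22 ± 0.065. Immediate early genes such as Egr2 and Npas4 were also lower, by 5.22-fold and 4.26-fold. Rises were smaller and led by Sfmbt2, a Polycomb group protein, at 4.10-fold.

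Of 18193 genes tested with limma, 2781 passed an adjusted p of 0.05, 1654 of them higher and 1127 lower in R6/2 mice. Large changes were mainly falls: 131 genes changed at least 2-fold, 100 of them lower and 31 higher. The groups of mice did not overlap for 2477 of the 2781 genes, and for 19.4% of all genes, against 2.86% by chance for 4 mice against 4. At the level of probe sets, 4566 of 45037 passed, 2497 higher and 2069 lower. The gene count was 1698 without wild-type mouse 48, 1679 without R6/2 mouse 70, 1399 without moderation of variances and 1252 with the cortical gene score described further on as a covariate, which raised the median standard error from 0.093 to 0.12 and left 5 residual degrees of freedom in place of 6. Without R6/2 mouse 64 the genes called higher numbered 995. The probe sets called numbered 2780 without R6/2 mouse 64, 2650 without R6/2 mouse 70 and 2656 without wild-type mouse 48.

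Falls of at least 3-fold that stood outside the medium spiny neuron and immediate early lists included Abi3bp, an extracellular matrix protein (at least 8.05-fold, its R6/2 mean of 3.51 in the range of the Y-linked probe sets), Ddit4l, an inhibitor of mTOR signalling (-2.17 ± 0.13, log2 and SE), the glutathione peroxidase Gpx6 (-1.78 ± 0.32), Gsg1l, an auxiliary subunit of AMPA receptors (-1.76 ± 0.14), the pro-apoptotic gene Hrk (-1.70 ± 0.13), Dmkn (-1.60 ± 0.20) and the small GTPase Rasl10a (-1.59 ± 0.25). Their adjusted p ranged from 2.92e-05 for Ddit4l to 0.00488 for Gpx6. The brighter probe set of Sdr39u1 fell by 2.19 on the log2 scale, while its other probe set differed by 0.087 ± 0.094 (adjusted p = 0.624). After Sfmbt2 (2.04 ± 0.12), the largest rises were those of AW551984 (1.99 ± 0.17), the calpain inhibitor Cast (1.50 ± 0.22), the protocadherin Pcdh20 (1.49 ± 0.15), Insyn2b (1.45 ± 0.13), the interferon-induced gene Ifit1 (1.28 ± 0.28) and Dleu7 (1.25 ± 0.11). They were followed by Sap30, a subunit of the Sin3 histone deacetylase complex, Trmt2b, the interferon-induced gene Rtp4, the cell cycle regulator Cks1b and Rgs19, with log2 changes between 1.18 and 1.21. Other probe sets moved less in AW551984 (0.14, adjusted p = 0.413, and 0.060, adjusted p = 0.639), Sfmbt2 (0.37, adjusted p = 0.0421), Pcdh20 (0.55, adjusted p = 0.00826), Cast (0.050 in 1 of 2, adjusted p = 0.806), Trmt2b (0.059, adjusted p = 0.641) and Hrk (-0.24, adjusted p = 0.250). Many of the genes that rose were dim in wild-type striatum, Sfmbt2 at 4.34 ± 0.26 and Ifit1 at 4.31 ± 0.30, against a median of 5.11 over all probe sets, and RMA values understate changes of dim genes.

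Of the 39 measured genes shared by medium spiny neurons, 32 fell, 1 rose and 6 did not pass the test, with a median log2 change of -0.77. Adjusted over the list alone, 34 were lower and 1 was higher. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, fell by 0.92 ± 0.090 (log2, SE). So did the phosphodiesterase gene Pde10a (-1.13 ± 0.12), the cannabinoid receptor gene Cnr1 (-1.46 ± 0.20), Arpp19 (-1.45 ± 0.10) and Rgs9, a striatal regulator of G protein signalling (-1.29 ± 0.094), each with an adjusted p of at most 0.00129. 1 of 2 other probe sets of Rgs9, dim at a mean of 4.53, was higher in R6/2 mice by 0.53 ± 0.10 (adjusted p = 0.0121). Another probe set of Cnr1 moved less (-0.35 ± 0.11, adjusted p = 0.0661). So did a bright probe set of Arpp19, at a mean of 10.42 (-0.29 ± 0.14, adjusted p = 0.241), while a further Arpp19 probe set fell by 1.06 ± 0.10 (adjusted p = 0.000480). The member that rose was the orphan receptor gene Gpr149 (0.91 ± 0.13, adjusted p = 0.00196, named after its values were seen). As a set the list was lower by camera (adjusted p = 2.75e-27, against adjusted p = 0.121 with an estimated correlation), and the list score of each R6/2 mouse, from -0.95 to -0.81, lay below that of each wild-type mouse, from -0.27 to 0.12.

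**Figure D1:**
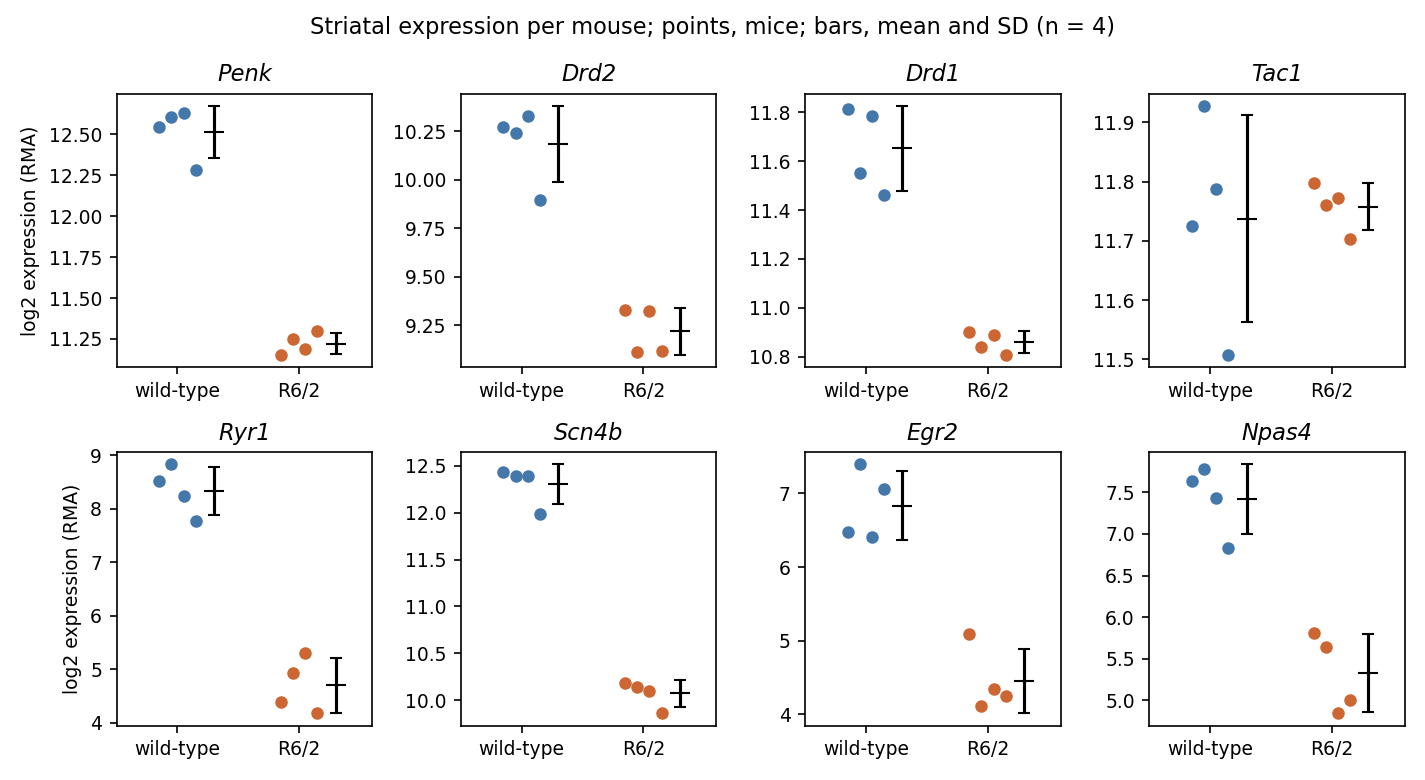
Striatal expression of 8 genes (vertical axes, log2 RMA values, each panel on its own scale that does not start at 0) in wild-type and R6/2 mice. Points are single mice and bars give the mean and SD of 4 mice. R6/2 and wild-type mice do not overlap in Penk, Drd2, Drd1, Ryr1, Scn4b, Egr2 and Npas4, and they do in Tac1.

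As a list, genes of the indirect pathway, the striatal output to the external pallidum, fell more than direct-pathway genes. The direct pathway is the output to the nigra. Of 8 measured indirect-pathway genes, 4 fell and 4 did not pass: Penk (-1.29 ± 0.088), the dopamine receptor gene Drd2 (-0.97 ± 0.11), the orphan receptor gene Gpr6 (-0.97 ± 0.11) and Plxdc1 (-1.02 ± 0.15). Another probe set of Plxdc1, at a mean of 5.40, differed by -0.031 ± 0.089 (adjusted p = 0.875). Of 11 direct-pathway genes, 3 fell, 1 rose and 7 did not pass. The dopamine receptor gene Drd1 (-0.79 ± 0.091), the dynorphin precursor Pdyn (-0.75 ± 0.11) and Slc35d3 (-0.51 ± 0.082) fell, and the transcription factor gene Isl1 rose by 0.37 ± 0.087, a call lost without R6/2 mouse 70 (adjusted p = 0.0583) or 78 (adjusted p = 0.0525). The substance P precursor Tac1 differed by 0.021 ± 0.091 (adjusted p = 0.908), and its sign was opposite without wild-type mouse 63 (-0.056). Adjusted over the list alone, 5 indirect-pathway genes were lower, and 4 direct-pathway genes were lower and 2 higher, and without 1 array 0 to 2 direct-pathway genes were called higher. The mean log2 change of the direct-pathway genes minus that of the indirect-pathway genes was 0.46 ± 0.056 in R6/2 mice against 0 ± 0.060 in wild-type mice (SD, n = 4 each, exact 2-sided permutation p = 0.0286, the smallest that 70 arrangements allow). The indirect list was lower by camera (adjusted p = 7.35e-05, against adjusted p = 0.215 with an estimated correlation). The direct list did not pass (adjusted p = 0.102), except in the set test named fry (adjusted p = 0.0491), without wild-type mouse 63 (adjusted p = 0.0386) and with the cortical score as a covariate (adjusted p = 0.0421).

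Immediate early genes, which neurons transcribe within minutes of activity, were lower: 13 of 25 fell, 1 rose and 11 did not pass, with 19 lower and 1 higher adjusted over the list alone, and 12 to 18 called lower and 0 to 1 higher without 1 array. Egr2 (-2.38 ± 0.25), Npas4 (-2.09 ± 0.24), Dusp1 (-0.86 ± 0.13) and Homer1 (-0.80 ± 0.11) fell, while Fosb rose by 0.49 (adjusted p = 0.0401, named after its values were seen). The list was lower by camera (adjusted p = 1.51e-10, against adjusted p = 0.215 with an estimated correlation), with a median of -0.62. The score of cortical projection neuron genes was -0.70 ± 0.46 in R6/2 mice against 0 ± 0.45 in wild-type mice, with overlapping groups (SD, n = 4 each, exact permutation p = 0.0857). Wild-type mouse 54, with a cortical score of -0.66, had the lowest immediate early score of the wild-type mice (-0.30), and R6/2 mouse 64, with a cortical score of -0.11, had the highest of the R6/2 mice (-0.40). With the cortical score as a covariate, 7 immediate early genes were called lower, the median was -0.30 and camera called the list (adjusted p = 1.08e-05). Per1, which is also a clock gene, fell by 0.46 ± 0.096, and Bdnf differed by -0.40 ± 0.14 (adjusted p = 0.0817).

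The cortical list itself had 3 of 17 members lower: Rasgrf2 (-0.85 ± 0.13), Slc30a3 (-0.67 ± 0.12) and Rtn4rl2 (-0.79 ± 0.23), with 7 lower adjusted over the list alone and 2 to 7 called lower without 1 array. The call of Rtn4rl2 was lost without any of 6 arrays, at most to adjusted p = 0.108 without R6/2 mouse 65. The list's call by camera (adjusted p = 1.53e-05) was lost with an estimated correlation (adjusted p = 0.245). Slc17a7, the vesicular glutamate transporter of cortical neurons, ranged from 5.80 to 8.66 among wild-type mice and from 5.08 to 7.64 among R6/2 mice. The ependymal and choroid plexus list varied as widely, with scores from -0.71 to 0.88 in wild-type and from -0.78 to 1.16 in R6/2 mice. In it Enkur rose (0.85 ± 0.15), Ccdc153 fell (-0.57 ± 0.13) and 17 of 19 members did not pass (camera adjusted p = 0.0933). The counts were equal adjusted over the list alone, and 1 to 2 members were called higher without 1 array.

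**Figure D2:**
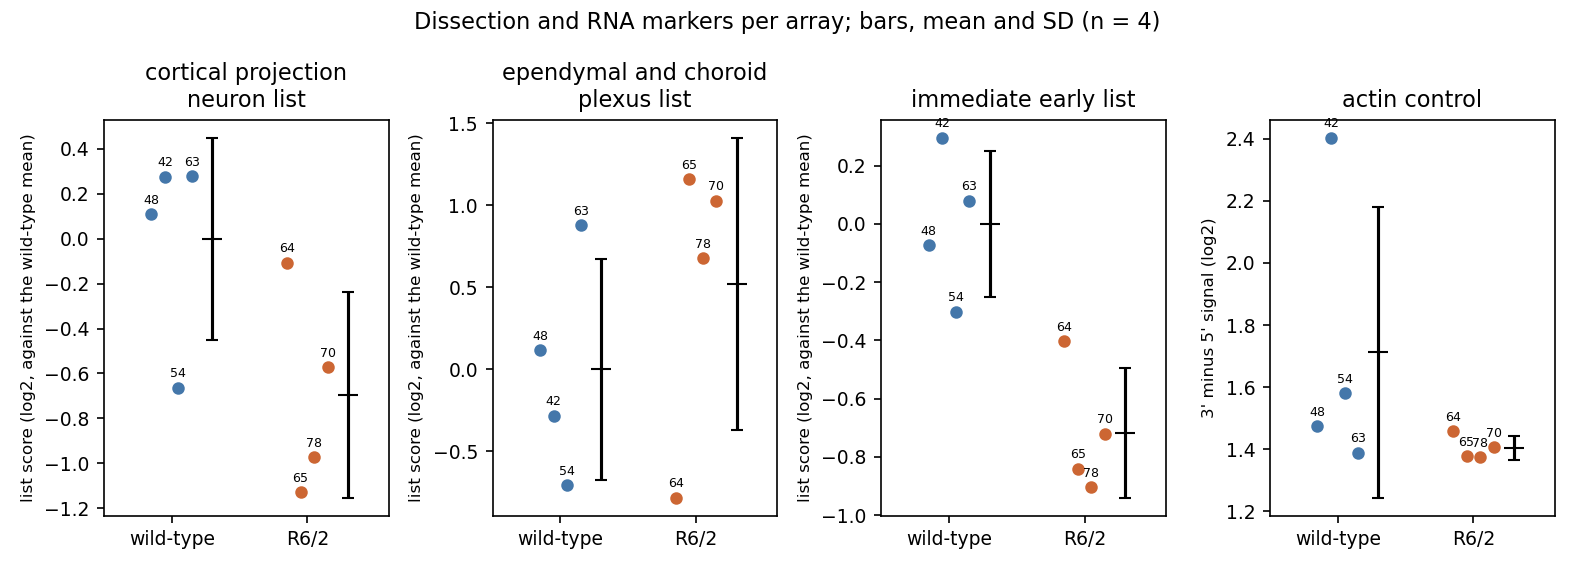
Scores of 3 gene lists (mean log2 value of the members against the wild-type mean) and the actin 3' minus 5' control signal (log2) for each array, labelled with the mouse number; vertical axes do not start at 0. Points are single mice and bars give the mean and SD of 4 mice. Cortical scores of the groups overlap, with wild-type mouse 54 at -0.66 and R6/2 mouse 64 at -0.11, and wild-type array 42 lies highest in the actin signal at 2.40.

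Genes for calcium handling, channels and synapses were lower as well, in lists that share members with earlier lists and with each other. Ryr1 and Kcnip2, for example, are also in the shared medium spiny neuron list, and Homer1 is in the immediate early list. Camk2a is in both the calcium handling and the postsynaptic list, so the counts are not independent. Of 46 calcium handling genes 25 fell and none rose, among them the kinase genes Prkcb (-0.73 ± 0.073) and Camkk2 (-1.20 ± 0.14) and the calmodulin-binding scaffold gene Strn (-1.12 ± 0.11). Of 30 postsynaptic density genes 18 fell and none rose, including the scaffold genes Shank3 (-0.80 ± 0.10) and Ddn (-0.73 ± 0.088), Kalrn (-1.02 ± 0.12) and the calcium/calmodulin-dependent kinase gene Camk2a (-0.70 ± 0.092). 1 of 7 other probe sets of Kalrn, at a mean of 7.12, differed by 0.39 ± 0.12 (adjusted p = 0.0630). Of the rest, some fell (-1.04, -0.72 and -0.50, adjusted p = 0.0213, 0.0238 and 0.0107). The others did not pass (-0.27, -0.10 and -0.0054, adjusted p = 0.305, 0.697 and 0.985). Of 40 potassium channel genes 15 fell and none rose, with Kcnip2 at -0.97 ± 0.10 and Kcnh3 at -0.75 ± 0.094. Other probe sets of Kcnip2 moved less (-0.53, adjusted p = 0.364, and -0.029, adjusted p = 0.869). Of 21 glutamate receptor genes 8 fell and none rose, led by Grik2 (-1.08 ± 0.086), and of 31 presynaptic genes 8 fell, led by Unc13a (-0.93 ± 0.13). Another probe set of Grik2, at a mean of 5.67, moved less (-0.38, adjusted p = 0.133). Without 1 array, 4 to 8 presynaptic genes were called lower, and 1 higher without wild-type mouse 42. Adjusted over the list alone, the lower members numbered 30, 21, 20, 10 and 12 in these 5 lists. Camera called all 5 lists lower with adjusted p of at most 0.00178, and with an estimated correlation their adjusted p was 0.121, 0.0934, 0.0921, 0.0921 and 0.303. Among 14 genes of GABA receptors and GABA synthesis, the receptor subunit genes Gabrd (-1.29 ± 0.11) and Gabrg3 (-0.39 ± 0.10) fell, Gabra5 rose by 0.57 ± 0.13, 11 did not pass, and the list did not pass (camera adjusted p = 0.206), with equal counts adjusted over the list alone, while fry called it (adjusted p = 0.0348). The call of Gabrg3 was lost without any of 5 arrays, at most to adjusted p = 0.0786 without wild-type mouse 48. Another probe set of Gabrd, dim at a mean of 3.49, differed by -0.067 ± 0.072 (adjusted p = 0.623). Beside these groups, the cortical score was -0.70 in R6/2 mice, and with it as a covariate 17 calcium handling, 14 postsynaptic, 8 potassium channel, 7 glutamate receptor and 4 presynaptic genes were called lower. The medians of these 5 lists were then -0.42, -0.47, -0.20, -0.22 and -0.065, against -0.49, -0.47, -0.28, -0.21 and -0.11, and camera called all 5.

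Of 20 neuropeptide genes 11 fell and 9 did not pass (11 lower adjusted over the list alone, 5 to 12 called lower without 1 array and 7 without wild-type mouse 42), with a median of -0.51 (camera adjusted p = 8.35e-07, against adjusted p = 0.121 with an estimated correlation). Chgb, a secretory granule protein, fell by 0.59 ± 0.13. Of 20 striatal interneuron genes 4 fell, namely the neuropeptides Npy (-0.72 ± 0.12), Sst (-0.47 ± 0.12) and Vip (-1.29 ± 0.36) and the nitric oxide synthase gene Nos1 (-0.51 ± 0.089), with 5 lower adjusted over the list alone and 2 to 4 called lower without 1 array (camera adjusted p = 0.000398, against adjusted p = 0.217 with an estimated correlation). The call of Sst was lost without any of 4 arrays (at most to adjusted p = 0.0655, without wild-type mouse 48) and that of Vip without any of 6 (0.0916, without R6/2 mouse 65). With the cortical score as a covariate, 4 neuropeptide and 2 interneuron genes were called lower, with list medians of -0.28 (against -0.51) and -0.14 (against -0.23), and camera called both lists. Npy, Sst and Vip are also expressed in cortical interneurons.

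None of the glial and vascular lists was called higher. Of 20 astrocyte genes 7 fell and none rose, among them the glutamate transporter gene Slc1a3 (-0.38 ± 0.076), Aldoc (-0.32 ± 0.070), Atp1b2 (-0.38 ± 0.10) and Ntsr2 (-0.64 ± 0.18), with 12 lower adjusted over the list alone and 2 to 7 called lower without 1 array (camera adjusted p = 2.98e-05, against adjusted p = 0.223 with an estimated correlation). Gfap, the intermediate filament of reactive astrocytes, differed by 0.034 ± 0.24 (adjusted p = 0.946), and its sign was opposite after quantile normalization and without wild-type mouse 48 or 54 or R6/2 mouse 78. None of 24 microglia genes passed with limma, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.536 for the list). Without 1 array, 1 was called higher (without R6/2 mouse 70) or 1 lower (without R6/2 mouse 64 or 78). Of these genes Ctss differed by 0.40 ± 0.12 (adjusted p = 0.0516, called without R6/2 mouse 70 at 0.00876 and in 4 alternatives over all arrays at 0.0303 to 0.0494) and Csf1r by -0.078 ± 0.090 (adjusted p = 0.617). Among 23 oligodendrocyte and myelin genes Fa2h (-0.64 ± 0.10), Mal (-0.56 ± 0.10) and Mobp (-0.38 ± 0.078) fell, Evi2a rose (0.39 ± 0.12) and 19 did not pass (4 lower and 1 higher adjusted over the list alone, 0 to 4 called higher without 1 array, camera adjusted p = 0.225). The progenitor list had 2 falls, Cacng4 (-0.96 ± 0.13) and Bcan (-0.44 ± 0.072), and 1 rise, Lhfpl3 (0.40 ± 0.11), in 11 genes (camera adjusted p = 0.144, fry adjusted p = 0.0107), and these counts held adjusted over the list alone. Of 23 endothelial and mural genes 5 fell, including the tight junction gene Cldn5 (-0.84 ± 0.14), the transporter gene Abcb1a (-0.58 ± 0.089) and the receptor gene Flt1 (-0.39 ± 0.090), with 6 lower adjusted over the list alone (camera adjusted p = 0.000582, against adjusted p = 0.223 with an estimated correlation). Calls near the threshold were lost without single arrays: Atp1b2 without any of 4 (at most to adjusted p = 0.0918, without R6/2 mouse 70), Ntsr2 without any of 4 (0.0824, without wild-type mouse 63), Evi2a without any of 7 (0.124, without wild-type mouse 48) and Lhfpl3 without any of 5 (0.0921, without wild-type mouse 48). With the cortical score as a covariate, no astrocyte gene and 2 endothelial genes were called lower, while the list medians were -0.24 (against -0.27) and -0.16 (against -0.13) and camera called both lists (adjusted p = 0.00171 and 0.000498).

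The lists that were higher concerned protein folding and degradation, respiration and interferon. Of 31 proteasome subunit genes 11 rose and none fell, each by a small amount: Psma2 by 0.39 ± 0.075, Psmb7 by 0.37 ± 0.079 and Psmb4 by 0.28 ± 0.070, with a list median of 0.20. The call of Psmb4 was lost without R6/2 mouse 64 (adjusted p = 0.0652), R6/2 mouse 70 or wild-type mouse 48. Of 21 heat shock and chaperone genes 5 rose, including the co-chaperone genes Stip1 (0.62 ± 0.081), Dnaja1 (0.43 ± 0.074) and Dnajb1 (0.46 ± 0.096). Of 61 nuclear-encoded oxidative phosphorylation genes 7 rose, among them Cyc1 (0.40 ± 0.079) and Atp5b (0.35 ± 0.072). That share is close to that over all genes, 1654 of 18193. The list median of 0.11 was near those of ribosomal protein genes with symbols that begin with Rpl (0.090) or Rps (0.092). Without the dimmest 40% of genes, the median of all genes was 0.058. A rise particular to respiration is therefore not shown. Of 24 interferon and antigen presentation genes 5 rose, including Ifit1, the immunoproteasome gene Psmb10 (0.58 ± 0.11) and Ifitm3 (0.63 ± 0.17, lost without any of 5 arrays, at most to adjusted p = 0.0748 without wild-type mouse 48). In this list R6/2 mouse 78 had the highest list score, at 0.84 against 0.066 to 0.38 in the other R6/2 mice. Wild-type scores, from -0.17 to 0.13, overlapped those of R6/2 mice (exact permutation p = 0.0857). Adjusted over the list alone, the higher members numbered 17, 5, 7 and 11, and without 1 array 2 to 12, 3 to 4, 2 to 9 and 2 to 7 were called higher. Camera called these 4 lists higher, with adjusted p of 1.74e-07, 0.000628, 0.000218 and 0.000157, and with an estimated correlation their adjusted p was 0.223, 0.215, 0.250 and 0.305. The interferon list did not pass by fry (adjusted p = 0.0609). Beside these groups, the Gapdh control signal showed more 3' excess in wild-type than in R6/2 arrays, at 0.66 ± 0.36 against 0.30 ± 0.055 (log2, SD, n = 4 each, exact permutation p = 0.0286, adjusted over 2 control genes p = 0.0571). Wild-type array 42 lay highest, at 1.19. The other wild-type arrays, at 0.41 to 0.52, also lay above the R6/2 arrays, at 0.23 to 0.35, so this signal cannot be told apart from genotype. Their actin signals overlapped (1.39 to 1.58 against 1.37 to 1.46). Without array 42, 8 proteasome, 3 heat shock, 5 oxidative phosphorylation and 4 interferon genes were called higher. The list medians were then 0.24, 0.20, 0.097 and 0.28, and camera called all 4. RNA quality beyond that array was not tested. With the cortical score as a covariate, these counts were 1, 3, 2 and 2, the list medians were 0.26, 0.19, 0.15 and 0.23, against 0.20, 0.17, 0.11 and 0.38, and camera called all 4.

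Of 21 cholesterol biosynthesis genes 8 fell and 2 rose, with Msmo1 at -0.76 ± 0.084, Insig1 at -0.73 ± 0.11, Idi1 at -0.66 ± 0.096 and the regulator Srebf2 at -0.57 ± 0.086 (9 lower and 2 higher adjusted over the list alone, 6 to 8 called lower and 1 to 2 higher without 1 array, camera adjusted p = 0.000635, against adjusted p = 0.245 with an estimated correlation). Of 18 circadian clock genes 7 fell and 1 rose, with Npas2 at -1.18 ± 0.086, Hlf at -0.68 ± 0.081 and Dbp at -0.48 ± 0.068 (8 lower and 1 higher adjusted over the list alone, 0 to 3 called higher without 1 array, camera adjusted p = 0.000676, against adjusted p = 0.0921 with an estimated correlation). The labels give no time of day. With the cortical score as a covariate, 5 cholesterol biosynthesis and 5 clock genes were called lower and none higher, with list medians of -0.084 (against -0.16) and -0.25 (against -0.30), and camera called both lists.

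**Figure D3:**
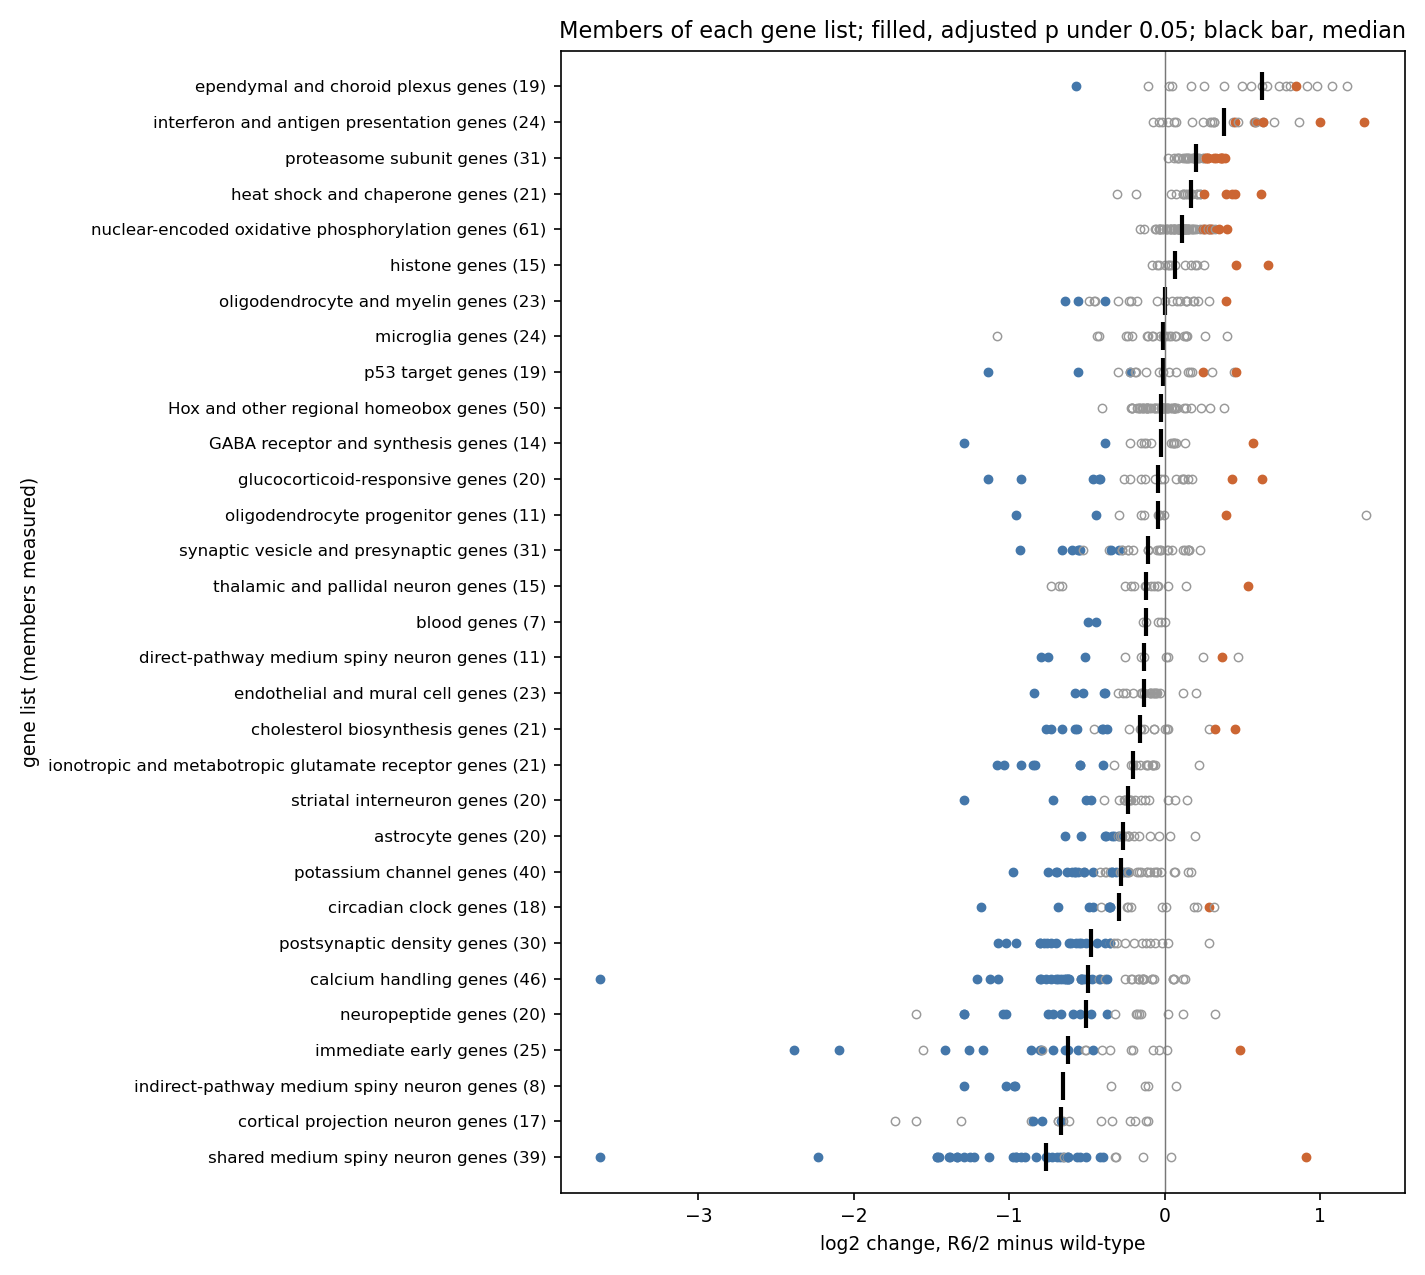
Log2 change between R6/2 and wild-type mice (horizontal axis) of every measured member of the 31 gene lists (rows, with the number of members measured). Each point is a gene, filled where its adjusted p was under 0.05 (blue lower, orange higher), and the black bar is the median of the list. Shared medium spiny neuron genes had the lowest median, -0.77, and ependymal and choroid plexus genes the highest, 0.63.

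Camera called none of the remaining 6 lists, while fry called 4 of them: glucocorticoid-responsive (adjusted p = 0.0159), p53 target (adjusted p = 0.0446), histone (adjusted p = 0.0369) and blood genes (adjusted p = 0.00945). Among 20 glucocorticoid-responsive genes 5 fell and 2 rose (4 to 5 lower and 0 to 2 higher without 1 array, camera adjusted p = 0.0933), with Cdkn1a at -1.14 ± 0.099, Gpd1 at -0.93 ± 0.12 and the metallothionein gene Mt1 at -0.41 ± 0.081. Among 19 p53 target genes 3 fell and 2 rose (2 to 3 lower and 1 to 3 higher without 1 array, camera adjusted p = 0.487), with Cdkn1a and Btg2 (-0.55 ± 0.11) lower and Polk (0.46 ± 0.097) higher. The histone genes H3c4 (0.66 ± 0.18) and H1f2 (0.46 ± 0.13) rose among 15 (camera adjusted p = 0.0953), and both calls were lost without single arrays, H3c4 at most to adjusted p = 0.0791 without R6/2 mouse 65 and H1f2 to 0.0771 without R6/2 mouse 64. Zfhx4 (0.53 ± 0.086) was the 1 call among 15 thalamic and pallidal genes (1 to 2 higher and 0 to 1 lower without 1 array, camera adjusted p = 0.206). The erythroid genes Hbb-b2 (-0.44 ± 0.092), which has near-identical copies, and Alas2 (-0.49 ± 0.13, adjusted p = 0.0771 without wild-type mouse 48) were lower among 7 blood genes (camera adjusted p = 0.0502). None of 50 Hox and other regional homeobox genes passed with limma, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.206 for the list). Onecut2 (0.38 ± 0.22, unadjusted p = 0.103) and Hoxa5 (0.063 ± 0.12, unadjusted p = 0.610) were not among these 3, and without 1 array 0 to 1 genes of the list were called lower and 0 to 1 higher. Counts of these 6 lists were the same adjusted over the list alone. Ppargc1a, a regulator of mitochondrial genes, differed by -0.029 ± 0.13 (adjusted p = 0.908), and its sign was opposite in the mean of all its probe sets (0.069) and without wild-type mouse 42 (0.057).

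Other probe sets of 16 named genes had the opposite sign. Besides Rgs9, Sdr39u1 and Kalrn, they were those of Rtp4 (-0.23), H1f2 (-0.20), Plk2 (0.29, against -0.22 for its brighter probe set), Tef (0.24, against -0.35), Rasgrf2 (0.10), Gpd1 (0.041), Kcnh3 (0.037), Nos1 (0.028) and Evi2a (-0.017), and those of the uncalled genes Gfap (-0.096), Htt (0.093), Tac1 (-0.071) and Ppargc1a (0.26). That of Rgs9 was the 1 called.

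Camera called 19 of the 31 lists, 15 lower and 4 higher, and none with an estimated correlation (7 lists at an unadjusted p under 0.05, lowest adjusted p = 0.0921), and fry called 25. Among the other splits of the 8 arrays into 4 and 4, 5 gave as many called lists, up to 22. All 5 were among the 16 that keep 3 mice of 1 genotype together, and the 18 that mix the genotypes evenly gave 1 to 9. The counts of called members rest on the tests of single genes.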

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

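The tests of cell share, of cortex and of wild-type array 42 as explanations were chosen after the values had been seen; the fits without 1 array and the counts over splits were planned.

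For the gene counts, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many called genes (2781, highest other split 8). The same held for genes changed at least 2-fold (131, highest other 7) and for called probe sets (4566, highest other 3). These counts come from the same arrays, and 1 of 35 is the smallest share this test allows. Every other split mixes the genotypes, so a true difference widens the spread within its groups and lowers its counts. The test argues against chance but cannot exclude it. For the number of lists called by camera chance stays open: 6 of 35 splits gave as many (19, highest other 22), though the 5 besides the real one each keep 3 mice of 1 genotype together, and the 18 even mixtures gave 1 to 9.

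The lower shared medium spiny neuron genes are a candidate for a change within these neurons. A smaller share of medium spiny neurons as the whole cause would raise the markers of other cells, if these are unchanged within their cells. The median log2 change of 90 markers of astrocytes, microglia, oligodendrocytes and endothelial cells was -0.11 (95% bootstrap interval over genes, taken as independent, -0.21 to -0.064). By list, the medians were -0.27 for astrocyte, -0.13 for endothelial, -0.0080 for microglia and 0.0040 for oligodendrocyte genes. Changes of these markers within their cells were not tested. The falls of the 32 members, chosen because they were called lower, ranged from -0.40 to -3.64, with an SD of 0.62 against a median standard error of 0.11. Without wild-type array 42 the list median was -0.78, against -0.77, which argues against RNA quality on that array. With the cortical score as a covariate the list median was -0.79. That score was lower in R6/2 mice on average (-0.70), and less cortex would not dilute striatal transcripts. This fit could therefore hardly have shrunk the falls, and no conclusion about cortex is drawn from it. A part played by cell loss together with lower expression per cell stays open, and the R6/2 genotype remains the biological explanation in the design, as a hypothesis.

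The lower immediate early genes may come in part or whole from different amounts of cortical tissue in the samples. Over all 25 measured members the median log2 change was -0.62 (SD 0.65), and with the cortical score as a covariate -0.30 (SD 0.62, 95% bootstrap interval over genes, taken as independent, -0.59 to -0.095). The interval lies below 0, and camera still called the list lower (adjusted p = 1.08e-05). But the median fell short of the bound for excluding cortex, which asked that most of its size be kept, and the called-lower members went from 13 to 7, in a fit with fewer residual degrees of freedom. With the covariate, Egr2 (-1.83, against -2.38) and Npas4 (-1.98, against -2.09) kept most of their falls. Nr4a2 (0.20, against -1.56) and Fos (-0.095, against -0.79), both uncalled, did not. The interval treats genes as independent, while their estimated correlation was 0.44. The cortical score was itself lower in R6/2 mice on average (-0.70), so the covariate can also take up a genotype difference. The fit therefore decides neither way, and for the list cortex as the whole cause stays open. Without wild-type array 42 the list median was -0.57, against -0.62, which argues against that array as the cause. Handling or arousal of the mice before tissue was taken was not tested.

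Single arrays far from the other 3 of their group were sought in 330 groups of 4 values (named genes, list scores and control signals); 12 were found, and chance gives about 16.5. Each is given with its gap to the nearest array as a share of the group's range. Wild-type array 63 was lowest in Scn4b (0.900), in Htt (0.870) and in the shared medium spiny neuron score (0.892), at -0.27 against 0.074 to 0.12. Wild-type array 54 was highest in Pdyn (0.890) and Cdkn1a (0.893), and wild-type array 48 in Grin2c (0.840). Wild-type array 42 was highest in Kdr (0.862) and in the Gapdh 3' minus 5' signal (0.863), at 1.19 against 0.41 to 0.52. R6/2 array 65 was lowest in Npy (0.841) and Psmb7 (0.972) and highest in the glucocorticoid score (0.964), and R6/2 array 78 was highest in Btg2 (0.934).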

How the results depend on the processing

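The cortical covariate was chosen after the data had been seen, the other alternatives before. Of the 121 called named genes, 78 were called in the same direction in every alternative over all arrays that kept them, and 101 without each array. Leaving out the dimmest 40% of genes removed some called named genes, such as Hbb-b2 and Alas2, which were not tested there. Plk2 was the 1 gene that changed sign (0.033 in the mean of all its probe sets). The called genes numbered 2781, and 1399 (819 higher, 580 lower) without moderation, 1252 (749 higher, 503 lower) with the cortical covariate, both with fewer degrees of freedom for the variance, and 1679 to 2545 without 1 array (921 to 1579 higher, 755 to 1122 lower). With the mean of all probe sets, 17 genes were at least 2-fold higher, against 31. Called probe sets ranged from 2650 to 4262 without 1 array, against 4566. Fewer arrays lower such counts. The camera calls fell from 19 lists to 0 with an estimated correlation, which lost the calls of the shared (-0.77), indirect-pathway (-0.65) and immediate early (-0.62) lists at unchanged medians. The indirect-pathway median was -0.38 with the mean of all probe sets and -0.97 without the dimmest 40% of genes. The direct-pathway list passed by fry (-0.13), with the cortical covariate (-0.10) and without wild-type replicate 63, its median ranging from -0.17 to -0.085 without 1 array. The direct against indirect difference ranged from 0.36 to 0.53. Ctss, uncalled, passed in 4 alternatives over all arrays (adjusted p 0.0303 to 0.0494). These signs turned, all of uncalled values: Gfap with quantile normalization (-0.0025) and from -0.20 to 0.29 without 1 array, Hoxa5 with the cortical covariate (-0.054) and from -0.068 to 0.15, Ppargc1a with the mean of probe sets (0.069), array weights (0.038) and the covariate (0.077) and from -0.12 to 0.057, Tac1 with the mean of probe sets (-0.025) and from -0.056 to 0.084. So did the test directions of the microglia (medians -0.092 to 0.050), oligodendrocyte (-0.068 to 0.12) and thalamic (-0.22 to -0.046) lists without 1 array. No blood gene was left among the brighter 60% of genes. The cause of these changes was not tested. Dim probe sets, near background, limit what RMA values can show.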

Other observations

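The gene families below were found by a scan of 295 families of symbols that share a stem and have at least 8 measured genes, for more called members in either direction than over all genes (hypergeometric test, adjusted over all families and both directions). Genes are named here after their values were seen. Regulators of G protein signalling (stem Rgs) were lower: 9 of 21 fell and 1 rose (adjusted p = 0.00114). Besides Rgs9, they included Rgs11 (-1.57 ± 0.097, log2 and SE), Rgs4 (-1.34 ± 0.19) and Rgs14 (-1.25 ± 0.12), while Rgs19 rose by 1.18 ± 0.11. Genes of calcium/calmodulin-dependent kinases and their inhibitors (stem Camk) were lower too, with 5 of 10 called (adjusted p = 0.0345), among them Camk2b (-0.62 ± 0.084) and Camk1g (-0.69 ± 0.13). Beside these families, the cortical score was -0.70 in R6/2 mice, and the scan was not repeated with it as a covariate or without 1 array.

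RNA polymerase genes (stem Polr) were higher, with 10 of 25 called and none lower (adjusted p = 0.0101): Polr3a rose by 0.87 ± 0.13 and Polr2a, the largest subunit of RNA polymerase II, by 0.76 ± 0.088. Families nearest the threshold that did not pass were zinc finger genes (Zfp, 50 of 336 higher, adjusted p = 0.0519), chaperonin genes (Cct, 5 of 9, adjusted p = 0.0671), regulatory proteasome genes (Psmd, 6 of 14, adjusted p = 0.0745), Trappc (6 of 14, adjusted p = 0.0745) and Snx (9 of 30, adjusted p = 0.0750). Further from it were Adcy (4 of 10 lower, adjusted p = 0.134), Car (5 of 16 lower, adjusted p = 0.134) and clustered protocadherins of the beta group (Pcdhb, 7 of 22, adjusted p = 0.136), near-identical copies whose probe sets can detect each other, with Pcdhb9 at 1.10 ± 0.13.

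Wild-type array 42 had the strongest 3' excess in its Gapdh (1.19) and actin (2.40) control signals, but not in that of pyruvate carboxylase (4.06, against 4.09 on R6/2 array 70), and the higher proteasome, chaperonin and RNA polymerase genes could in part come from its RNA. The test and its bound were fixed before the result was seen, and the interval was added afterwards: 76.2% of the 21 called members of these 3 families (95% Wilson interval 54.9 to 89.4) were still called higher without array 42, against 81.6% of all called-higher genes. The median log2 change of the 21 genes was 0.36, and 0.37 without the array. The share met the bound of 75% set for excluding the array, but its interval spans that bound, so the count of calls decides nothing. The median, no smaller without array 42, argues against that array as the source of the size of these rises. The genotype was not separated from the higher Gapdh 3' signal of the other wild-type arrays (0.41 to 0.52, against 0.23 to 0.35 on R6/2 arrays).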
